A study of Juglans regia with 6 samples.

How the data were processed

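Annual walnut branches were sampled in a control group and in a group inoculated with Phomopsis capsici, with 3 biological replicates each by the design text, which names no shared tree, batch or day. Per the labels' protocols, 1.3 ug of total RNA per sample was made into libraries with the NEBNext Ultra kit for Illumina, with random primers and cDNA selected at about 250 to 300 bp. No label states that the kit kept strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, fastp 0.19.7 and HISAT2 2.0.5 were used. The counter, the differential expression tool and the genome build are not given in the sources used here. Coordinates are those of the deposited table, whose scaffolds have names starting with NW.

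The deposited table covers 5634 genes on 2263 scaffolds. The authors deposited raw counts per gene and library. The normalized signal that the authors deposited is the count divided by 1 size factor per library; the ratio of both columns gave the same factor for all genes of a library, namely 1.13, 1.10 and 1.09 for control replicates 1 to 3 and 0.925, 1.00 and 0.823 for inoculated replicates 1 to 3. The FPKM values that the authors deposited rest on library sizes proportional to these factors, so they do not reveal the true totals, and they were not used further. The log2 fold change in the authors' deposited table is inoculated over control. The authors' deposited p-value columns hold unadjusted and adjusted p. With the rows of smallest p left out, 79.2% of the remaining rows gave a whole rank (within 0.01) for an adjustment over 28290 genes. The next best number gave 2.85%. The largest adjusted p listed is 0.0500 and no absolute log2 fold change is under 1. The adjusted values imply 7333 genes past the threshold, 1699 of which are not in the table used here, under the minimum fold change as far as the listed values show.

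Counts were tested with edgeR 4.0.16 (R 4.3.3; limma 3.58.1) by glmQLFit and glmQLFTest on the group, two-sided, after filterByExpr, which removed 798 of the 5634 genes and left 4836. Gene values are normalized counts as mean ± SD over 3 libraries; SE of a log2 fold change is its absolute value over the root of the F statistic. The design written before the data were examined named TMM normalization and adjustment over the tested genes. It was changed once the table proved to hold only genes that had been called, and before any number of calls was known. TMM assumes that most genes do not change, and adjustment over selected genes alone is too lenient. The authors' size factors were used instead, and Benjamini-Hochberg adjustment was made over 28290 genes, counting each one outside the fit as not passing. TMM and adjustment over the listed genes are given as alternatives. Because the genes were selected on these counts, p-values of a retest are not independent of that selection. The fitted log2 fold changes correlated with the deposited ones at 0.9993 across genes, and all 4836 had the same sign.

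Genes were assigned to 45 lists by patterns on their deposited descriptions, fixed before the data were examined; 42 had at least 5 listed members and were tested. Each test was Fisher's exact test, two-sided, of higher against lower genes in the list against all other listed genes, adjusted over 42 lists. Genes are not independent, so camera with a preset and with an estimated correlation and fry were run on limma-voom values of the fitted genes. Lists for photosynthesis, xylem, phloem, periderm and dividing cells stand for tissues a branch sample can hold. Named genes were, by a rule fixed beforehand, the 8 largest rises and 8 largest falls past the threshold with a description, no overlap between the groups and a mean of at least 100 in the higher group, and in each list the 2 genes of smallest p in the more frequent direction and the 1 of smallest p in the other. Genes described only as uncharacterized were treated as having no description, and some genes that the rule gives are left out of the text. The transcript most abundant in inoculated replicates 2 and 3, described in the closing part, was chosen after its values were seen.

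Where a group had no count, the fold is a lower bound against 3 counts over that group's libraries. With 1 to 3 counts, a ratio of summed counts has an exact 95% interval, which covers counting error only, since PCR reads are not independent molecules. Of 5322 listed genes with a RefSeq gene identifier, 4523 matched the gene table of the Walnut 2.0 assembly by gene name or identifier. That is a different assembly, from which no coordinate was taken. No sequence was compared, so a gene listed there under another name also counts as having no match. A further 312 entries are transcripts without a RefSeq identifier, whose IDs begin with the word for new models in the deposited table.

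Counts were simulated from the control means at a dispersion of 0.1, and 5284 genes passed the filter. Of all genes planted as changed, including those the filter removed, edgeR recovered 16.0% at 2-fold and 87.0% at 4-fold. False genes made up 4.63% of its calls. These calls were adjusted over the simulated genes alone. That is more lenient than the main adjustment over 28290 genes, so these shares do not describe the main test. The simulated dispersion is near the one of the inoculated branches. The controls varied more, with a biological coefficient of variation of 0.662. For both reasons, recovery in these data is expected to be lower. Random lists drawn from the listed genes passed Fisher's exact test at an unadjusted p under 0.05 in 3.69% of 840 draws. Alternatives were the RLE, upper quartile, TMM and listed-count scalings, other filters, DESeq2 1.42.0 and limma-voom, the replicate number as a block, other thresholds, and each library left out in turn. Python with pandas 2.3.3, numpy 2.4.6, scipy and matplotlib made the tables and plots.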

Results

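RNA was sequenced from annual branches of walnut (Juglans regia), a nut and timber tree. Branches of 1 group had been inoculated with Phomopsis capsici, the fungus that the labels name as the walnut branch blight pathogen, and branches of the other group were controls. Each group had 3 biological replicates by the design text, so 6 libraries entered the comparison. The question it addresses is how the transcriptome of walnut responds to this infection. No time after inoculation is given in the labels, and the metabolome that the design text mentions was not analysed here.

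The gene table held 5634 genes, each of which the authors had called as different between the groups, with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The counts of these genes summed to between 3412616 in control replicate 3 and 4545354 in inoculated replicate 2. The full depth of the libraries is unknown, since genes outside the list carry the rest of the reads.

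The 3 inoculated branches resembled each other more closely than the 3 controls did. Across the listed genes, the Pearson correlation of log2 normalized counts lay between 0.964 and 0.978 for pairs of inoculated libraries, against 0.629 for control replicates 1 and 2, 0.769 for 1 and 3 and 0.860 for 2 and 3. Genes are not independent replicates, so these values describe the libraries only. The biological coefficient of variation was 0.662 among controls and 0.309 among inoculated branches. Control replicate 1 stood nearer to the inoculated libraries, with correlations of 0.664 to 0.677, than control replicates 2 and 3 did, with 0.489 to 0.530.

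**Figure D1:**
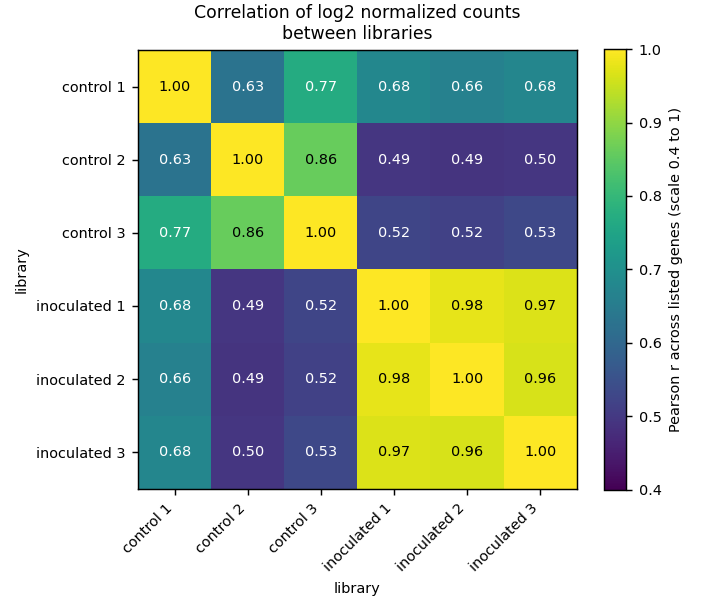
Pearson correlation across the 5634 listed genes (colour, scale from 0.4 to 1) between each pair of the 6 libraries, which stand on both axes; the values use log2 normalized counts. The 3 inoculated libraries form a block at 0.964 to 0.978, while the control pairs range from 0.629 to 0.860.

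In inoculated branches, genes for ribosomal proteins, the protein parts of the cytosolic ribosome, and for ERF transcription factors, regulators of ethylene and drought responses, were mostly higher. Genes of photosynthesis and genes for histones and the cell cycle were mostly lower. These 4 lists passed Fisher's exact test, but none passed camera, which allows for correlated genes, with an estimated correlation (adjusted p = 0.848, 0.848, 0.869 and 0.910). No list at all passed camera in that form, where the smallest unadjusted p was 0.0362, for LEA proteins and dehydrins. Not passing it therefore does not set these 4 lists apart from the others. Genes for beta-1,3-glucanases, lignin synthesis and the phloem also lay mostly on the lower side, without passing the test over the 42 gene lists tested. Of the 5634 listed genes, 1911 (33.9%) were higher and 3723 were lower. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the 28290 genes that the authors tested, 1637 of the 4836 fitted genes passed, 614 of them higher and 1023 lower. At an unadjusted p under 0.05, 4826 passed.

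These genes had been chosen by the authors' own test on the same counts, so the retest is not independent evidence. The split of calls depends on how libraries are scaled. RLE, TMM and upper quartile factors were estimated on the listed genes, of which most are lower. By construction they pull such genes towards balance. Turns to the higher side under them, here and in the lists below, are therefore in part set by the selection. With size factors estimated on the listed genes by DESeq2's method (RLE), 1681 genes were higher and 490 lower, by TMM 1235 and 695, by upper quartile 1379 and 630, and by listed counts alone 344 and 2225; these scalings moved the median log2 fold change by 0.89, 0.42, 0.53 and -0.55. Without control replicate 1 there were 3295 genes past the threshold, without control replicate 3 there were 203, and without any 1 of the inoculated replicates there were 0 in edgeR, with 3812 to 3952 at an unadjusted p under 0.05; with all libraries, DESeq2 called 4299 and limma-voom 1386.

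Several genes went from no or almost no reads in controls to high levels in inoculated branches. Whether reads of the fungus aligned to walnut scaffolds could not be tested here, so counts that are higher after inoculation are not shown to be of walnut origin alone. The gene with the smallest adjusted p was LOC109020307, which encodes the probable amido synthetase GH3.1, a kind of enzyme that joins the hormone auxin to amino acids; it lies on scaffold NW_017437188.1 from 15751 to 19503. It rose from 7.87 ± 3.02 to 3019.6 ± 263 normalized counts (SD, n = 3 per group), a log2 fold change of 8.56 ± 0.45 (SE; edgeR adjusted p = 0.00423). An unannotated transcript on scaffold NW_017388862.1 (249008 to 251929) whose description is also GH3.1 fell from 143 ± 31.1 to 8.23 ± 4.65, a log2 fold change of -4.11 ± 0.59 (adjusted p = 0.0180), and how reads shared by such copies were counted is not given in the sources used here. LOC109017527 (diphthamide biosynthesis protein 3-like, scaffold NW_017419223.1, 11302 to 12714) had no count in any control and 325 ± 49.5 in inoculated branches, at least 359-fold higher against a floor of 3 counts over the group. LOC108995686, a MADS-box factor resembling ANR1, was likewise at 0 in controls and at least 211-fold higher. LOC109012599, for the thaumatin-like protein 1b, had 1 count in the controls together and 565 ± 262 normalized counts after inoculation, a ratio of 1933 with a 95% counting interval of 346 to 76378. LOC109002982 (UPSTREAM OF FLC-like), LOC108990026 (LURP-one-related 10-like), LOC109016167 (a beta-glycosidase) and LOC108987382 (an aldo-keto reductase) also rose, each with 1 to 3 counts in the controls. Intervals and floors here cover counting error only.

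Most of the genes named for the largest falls had no count in any inoculated branch. LOC109011564, an SPX domain membrane protein gene on scaffold NW_017389773.1 (14628 to 23319), had 966 ± 442 normalized counts in controls and was at least 883-fold lower. LOC108991293 (ABC transporter C family member 8-like) was at least 757-fold lower, and LOC109003364, a lectin receptor kinase gene resembling CES101, at least 352-fold lower. LOC109010550 (copper-transporting ATPase PAA2-like) was at least 302-fold lower. LOC109018935, for a putative disease resistance protein, was at least 228-fold lower. LOC108987463, which resembles the sugar transporter SWEET17, fell from 158 ± 156 normalized counts, at least 144-fold. LOC109005969 (a leucine-rich repeat receptor kinase) and LOC108988367 (a WAT1-related protein) kept 3 and 1 counts over the inoculated libraries, against 2151 ± 2271 and 816 ± 845 normalized counts in controls. Their ratios were 1965 and 2216, with 95% counting intervals of 672 to 9531 and 397 to 87564. Of the genes named for these rises and falls, LOC109017527, LOC109003364, LOC109010550 and LOC108987463 had no match in the gene table of the later Walnut 2.0 assembly, a property that was more frequent among genes near 0 in 1 group (21.8% for genes near 0 after inoculation and 50% for genes near 0 in controls, against 9.28% of other listed genes of that level). The same held for LOC109015781, LOC109015148, LOC108991161, LOC108980517, LOC108983539 and LOC109002743, genes of the lists described next.

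**Figure D2:**
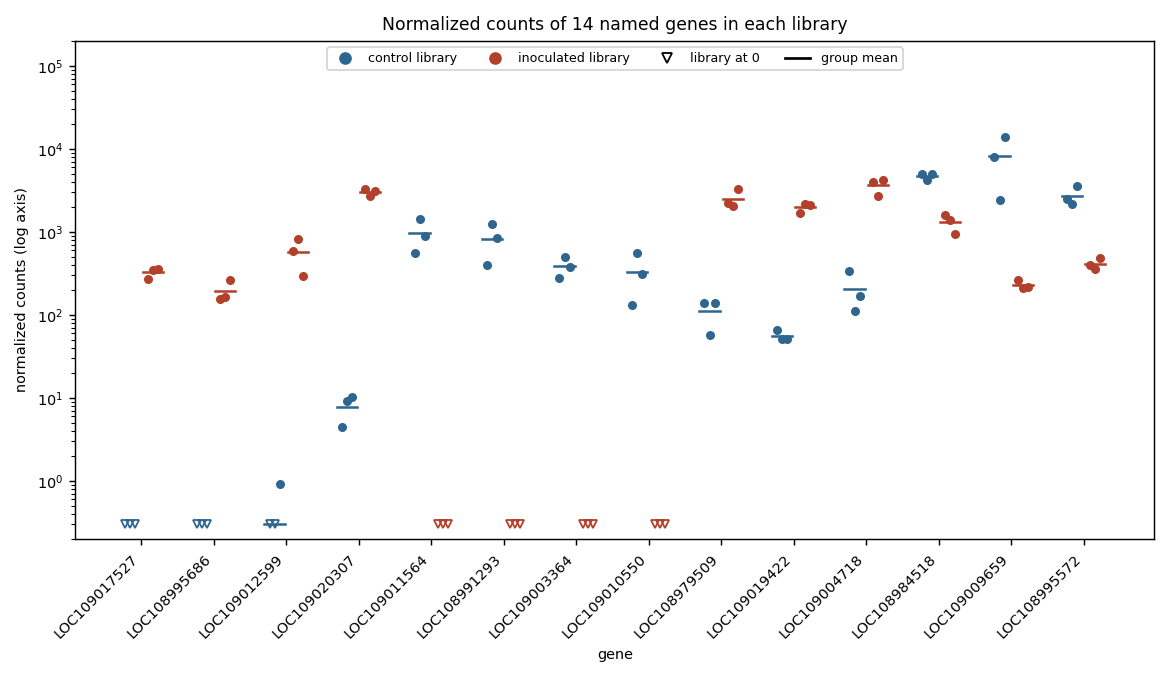
Normalized counts (log axis) of 14 named genes in each of the 3 control and 3 inoculated libraries; points are libraries, bars are group means, and open triangles at the base mark libraries at 0. For LOC109020307 the inoculated libraries lie between 2726 and 3233 and the controls between 4.43 and 10.1, while LOC109011564 is at 0 in every inoculated library.

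Genes for cytosolic ribosomal proteins were mostly higher. Of 94 listed members, 82 were higher, or 87.2% (Fisher's exact test, two-sided, adjusted p = 1.73e-25 over 42 lists), with a median log2 fold change of 1.41 in the authors' deposited table. The list passed camera with a preset correlation (adjusted p = 4.85e-14) but not with an estimated one (adjusted p = 0.848), and among members with an absolute log2 fold change of at least 2, 12 were higher and 12 lower. In edgeR 49 rose and 4 fell. Adjusted over the list alone, all 88 fitted members passed. That outcome was largely fixed by the selection, since 4826 of the 4836 fitted genes had an unadjusted p under 0.05. Here and in every list below, passing adjusted over the list alone is therefore no evidence about the list. LOC108997235, for 60S ribosomal protein L30, rose from 2380 ± 562 to 14453 ± 2918 normalized counts, a log2 fold change of 2.60 ± 0.32 (adjusted p = 0.0139). LOC109019422, for the fusion of ubiquitin with L40, rose by 5.16 ± 0.33 on the log2 scale (adjusted p = 0.00578), while an unannotated transcript on scaffold NW_017441970.1 (4330 to 6443), which resembles the same fusion protein, fell by 8.01 ± 0.54 (adjusted p = 0.00634). How reads shared by such near-identical copies were counted is not given in the sources used here, so the values of this pair are uncertain. Members that rose and fell numbered 52 and 11 without control replicate 1, and without control replicate 3 only 3 rose and 2 fell.

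ERF transcription factor genes were mostly higher. Of 37 listed, 29 were higher (78.4% against 33.6% of other listed genes; Fisher's exact test, adjusted p = 7.40e-07). The list passed camera with a preset correlation (adjusted p = 0.000874) but not with an estimated one (adjusted p = 0.848). In edgeR 6 rose and 0 fell, with all 32 fitted members past the test adjusted over the list alone. Under RLE, TMM and upper quartile scaling 20, 12 and 15 passed as higher and 0 as lower. With listed-count scaling 6 passed as higher and 3 as lower. LOC108979509, resembling the dehydration-responsive factor DREB3, rose from 111 ± 46.7 to 2497 ± 680 normalized counts, a log2 fold change of 4.49 ± 0.47 (adjusted p = 0.0104). LOC108992253, resembling RAP2-1, rose by 2.95 ± 0.38 (adjusted p = 0.0145). Neither of these genes had a match in the Walnut 2.0 table. Without control replicate 1, 13 ERF genes rose and 3 fell, and without control replicate 3 only 1 rose.

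Genes for LEA proteins and dehydrins, which protect cells during water loss, gave 8 of 11 listed members higher (Fisher's exact test, adjusted p = 0.0690). The list passed camera with a preset correlation (adjusted p = 0.0313) but not with an estimated one (adjusted p = 0.848). In edgeR 6 rose and 1 fell, and all 10 fitted members passed adjusted over the list alone. LOC109004718, for LEA protein D-29, rose from 204 ± 116 to 3643 ± 822 normalized counts, a log2 fold change of 4.16 ± 0.50 (adjusted p = 0.0135), and LOC109015781 (D-11-like) rose by 2.93 ± 0.48. LOC108982947, resembling the ABI5 factors that act in abscisic acid signalling, rose to 20443 ± 2690 from 2857 ± 1744 normalized counts. Of 29 listed genes of the abscisic acid list 10 were higher, or 34.5%, against 33.9% of other listed genes. Its direction thus matched that of the listed genes as a whole. In edgeR LOC108982947 was the 1 member that rose, and 7 fell. Among those that fell were LOC109015148 and LOC109014541, with 2 and 1 counts over the inoculated libraries. Both encode protein phosphatases of the 2C class, of which some restrain abscisic acid signalling. Under RLE, TMM and upper quartile scaling the calls of the abscisic acid list went the other way, with 10, 7 and 8 higher and 4, 6 and 5 lower. They were 4 and 13 without control replicate 1 and 0 and 1 without control replicate 3. Without control replicate 3, 1 LEA gene rose and none fell.

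Genes of photosynthesis were mostly lower. Of 42 listed, 38 were lower (Fisher's exact test, adjusted p = 0.00459), and the list passed camera with a preset correlation (adjusted p = 0.0275) but not with an estimated one (adjusted p = 0.869). In edgeR 13 fell and 1 rose, and all 40 fitted members passed adjusted over the list alone. LOC108984518, for subunit XI of photosystem I, fell from 4687 ± 396 to 1296 ± 327 normalized counts, a log2 fold change of -1.85 ± 0.29 (adjusted p = 0.0224). LOC109011866, for photosystem I subunit O, had a log2 fold change of -2.88 ± 0.49 (adjusted p = 0.0259). The 1 member that rose, an unannotated transcript on scaffold NW_017443560.1 (1586609 to 1587619), resembles a ferredoxin-dependent glutamate synthase, an enzyme of ammonium assimilation. Under RLE scaling 4 members passed as higher and 2 as lower, under upper quartile 4 and 3; without control replicate 1, 32 fell, and without control replicate 3 none passed.

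Genes for histones and the cell cycle, which mark dividing cells such as those of the cambium, were lower in 43 of 47 cases (Fisher's exact test, adjusted p = 0.00104), though the list did not pass camera with a preset (adjusted p = 0.0957) or an estimated correlation (adjusted p = 0.910). In edgeR 8 fell and 2 rose, and all 42 fitted members passed adjusted over the list alone. A histone H4 gene, LOC109021742, was at 0 in all inoculated branches and at least 75.1-fold lower; it had no match in the Walnut 2.0 table. LOC109009318, for the spindle kinesin KIN-5C, had a log2 fold change of -4.10 ± 0.68 (adjusted p = 0.0241). LOC109006958, for a cyclin-dependent kinase inhibitor, which holds back cell division, rose by 4.83 ± 0.73 (adjusted p = 0.0210). Without control replicate 2, 28 members fell, without control replicate 3 none did, and under RLE scaling 4 passed as higher and 3 as lower.

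Phloem genes were lower in 11 of 11 cases (Fisher's exact test, adjusted p = 0.0845), and 5 fell and 0 rose in edgeR, with all 9 fitted members past the test adjusted over the list alone. A pair of genes for sieve element occlusion proteins, which form filaments that can plug damaged sieve tubes, had large changes. LOC109009659 fell from 8096 ± 5663 to 228 ± 27.3 normalized counts, a log2 fold change of -5.15 ± 0.66 (adjusted p = 0.0145). LOC108986226 had a log2 fold change of -5.36 ± 0.76 (adjusted p = 0.0177). In the list for secondary wall and xylem, 8 of 9 listed genes were lower, but 1 gene fell (LOC108991161, a fasciclin-like arabinogalactan protein) and 1 rose (LOC108988953, IRX15-LIKE); under RLE, TMM and upper quartile scaling 1 passed as higher and 0 as lower, and without control replicates 1 and 2 in turn 4 and 5 fell. Without control replicate 1, 8 phloem genes fell, without control replicate 2, 9 did, and without control replicate 3, 2 did.

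None of the lists of defence genes described next passed Fisher's exact test over the 42 lists. Of 24 genes for beta-1,3-glucanases, which cut callose and fungal wall glucans, 22 were lower (Fisher's exact test, adjusted p = 0.0665); 10 fell and 1 rose, and all 20 fitted passed adjusted over the list alone. LOC108995572 had a log2 fold change of -2.72 ± 0.32 (adjusted p = 0.0129), while LOC108980517 rose by 4.22 ± 0.88. Among 78 NLR genes, which encode intracellular immune receptors, 61 were lower (adjusted p = 0.0845); 20 fell and 3 rose, with 57 of 58 fitted past the test adjusted over the list alone. LOC109004983, for an RPP13-like protein, had a log2 fold change of -4.70 ± 0.62 (adjusted p = 0.0158), and LOC108992470, resembling the TMV resistance protein N, rose by 4.87 ± 0.56 (adjusted p = 0.0124). Of 28 genes for other pathogenesis-related proteins, 6 fell and 1 rose; LOC109013660 (PR5) fell from 643 ± 432 to 39.1 ± 4.52 normalized counts, and the gene that rose was the thaumatin-like LOC109012599 named above. None of the 9 listed chitinase genes passed in edgeR (7 of 7 fitted passed adjusted over the list alone), while 5 passed as lower in DESeq2 and 2 as higher under RLE scaling in edgeR. Under RLE scaling the calls turned to 13 higher and 10 lower for NLR genes and 4 and 3 for the pathogenesis-related list. Falls without control replicate 1 went to 15 for glucanases, 39 for NLR genes, 11 for the pathogenesis-related list and 4 for chitinases, and without control replicate 2 to 16, 33, 13 and 0. Without control replicate 3, 1 glucanase gene fell and 0 rose, 2 NLR genes rose and 1 fell, and 1 pathogenesis-related gene rose and 1 fell.

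Of the 13 genes of the core phenylpropanoid pathway, 12 were lower, 3 fell and 0 rose (Fisher's exact test, adjusted p = 0.205), and of 17 lignin genes 16 were lower, 2 fell and 1 rose (adjusted p = 0.0821). LOC109021248, resembling phenylalanine ammonia-lyase, the entry enzyme of the pathway, had a log2 fold change of -3.03 ± 0.63 (adjusted p = 0.0392). LOC108999180, for caffeoyl-CoA O-methyltransferase 5, fell from 1465 ± 1283 to 127 ± 34.0 normalized counts. The 1 lignin list member that rose, LOC108988430, encodes a spermidine hydroxycinnamoyl transferase, an enzyme of phenolamide rather than lignin synthesis. In flavonoid synthesis 3 rose and 3 fell of 14 (adjusted p = 1). LOC108994581 (leucoanthocyanidin reductase-like) had a log2 fold change of -4.18 ± 0.52 (adjusted p = 0.0142) and LOC109020619 (flavonoid 3'-monooxygenase-like) rose by 6.57 ± 1.15 (adjusted p = 0.0269). All fitted members of these lists, 13, 12 and 14, passed adjusted over the list alone; without control replicate 3, 1 flavonoid gene fell and no other member passed. Of lignin genes 9 fell without control replicate 1, and without control replicate 2, 7 lignin, 7 core and 9 flavonoid genes did. Under RLE and upper quartile scaling 1 core gene passed as higher and 1 as lower, and flavonoid calls were 5 higher and 2 lower under RLE, 4 and 3 under TMM and upper quartile, and 3 and 5 with listed-count scaling.

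Hormone genes changed in both directions. Of 50 auxin genes, 41 were lower (Fisher's exact test, adjusted p = 0.0821); 14 fell and 2 rose, among the latter LOC108983539, for the auxin-responsive protein IAA4. In the list for ethylene synthesis and signalling, 4 fell and 1 rose of 18 (adjusted p = 0.329). LOC108981058 and LOC109001586 are both described as 1-aminocyclopropane-1-carboxylate oxidase homolog 4-like, so their place in ethylene synthesis rests on that description alone. The pair differed in direction. LOC108981058 had 2 counts over the inoculated libraries and was lower by a ratio of 522, with a 95% counting interval of 144 to 4314. LOC109001586 rose by 4.44 ± 0.48. In the jasmonate list 3 fell and 1 rose of 14 (adjusted p = 0.941). LOC109002743, resembling allene oxide cyclase, which acts in jasmonate synthesis, had a log2 fold change of -4.20 ± 0.65, and LOC108980095, a TIFY repressor gene, rose by 2.65 ± 0.61. Of 18 listed WRKY genes, LOC108989105 (WRKY51) rose by 3.81 ± 0.54, LOC108979107 (WRKY40) had a log2 fold change of -2.27 ± 0.51 and no other passed in the main fit. All fitted members of these 4 lists, 46, 15, 10 and 16, passed adjusted over the list alone. Without control replicate 3, 1 ethylene gene rose and 1 fell and no member of the other lists passed, whereas without control replicate 1 falls went to 33 for auxin, 7 for ethylene, 8 for jasmonate and 9 for WRKY genes, with 5, 1, 1 and 3 rises. Without control replicate 2, 15, 6, 5 and 0 fell and 2, 3, 0 and 2 rose. Under RLE, TMM and upper quartile scaling 3 ethylene genes passed as higher and 1 as lower, and under RLE 4 and 3 jasmonate genes. Auxin calls stayed mostly lower, with 7 higher and 12 lower under RLE and 3 and 12 under TMM and upper quartile. With listed-count scaling 1 auxin gene passed as higher and 27 as lower. WRKY calls were 4, 3 and 3 higher under RLE, TMM and upper quartile, with 0 lower, so that WRKY40 did not pass there; in DESeq2 they were 4 higher and 9 lower.

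**Figure D3:**
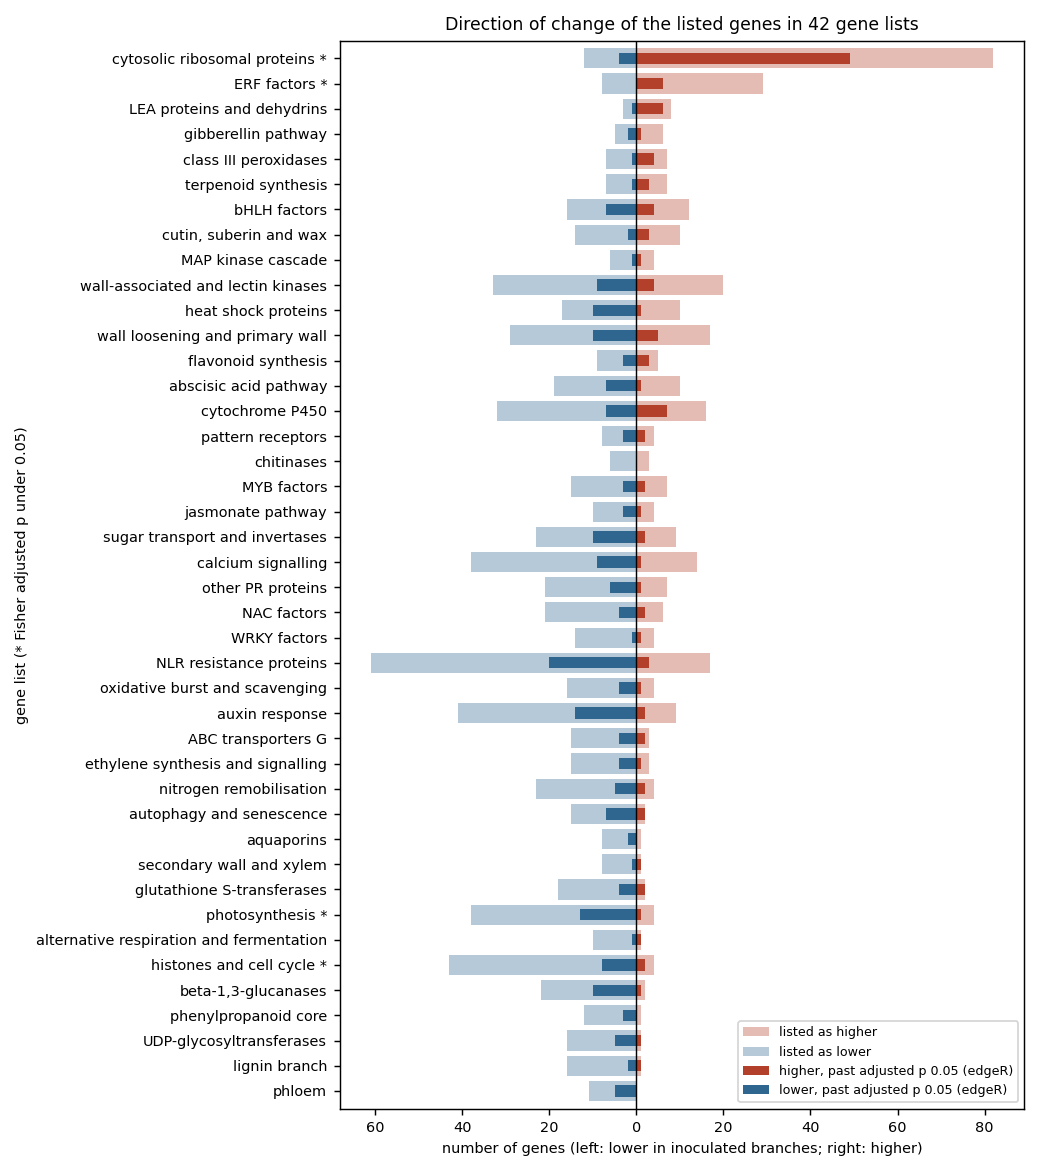
Numbers of genes (horizontal axis, lower to the left and higher to the right) in each of 42 gene lists (vertical axis); pale bars are genes in the authors' list and dark bars those past an adjusted p of 0.05 in edgeR, and an asterisk marks lists past an adjusted p of 0.05 in Fisher's exact test. Cytosolic ribosomal proteins have 82 of 94 members on the higher side, and phloem genes 11 of 11 on the lower side.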

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

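No named gene changed the sign of its fitted log2 fold change in a setting that fitted it (4 of the 129 were not fitted under RLE, 2 each under TMM and upper quartile, and 1 each with listed-count scaling and without control replicates 2 and 3). Calls did not hold: under RLE those of photosynthesis turned to 4 higher and 2 lower and those of histones and the cell cycle to 4 and 3. Adjustment over the listed genes alone and TMM as an alternative were chosen after seeing the data; the other settings were fixed before. Of 1637 genes (614 higher, 1023 lower; 37.5% higher), listed-count scaling gave 2569 (344 and 2225; 13.4%), RLE 1681 higher and 490 lower (77.4%), TMM 1235 higher (64.0%), and upper quartile 1379 and 630 (68.6%). These 4 scalings were estimated on listed genes, of which most are lower, and by construction RLE, TMM and upper quartile pull such genes towards balance. With no filter beyond a total above 0 there were 676 (263 and 413), at an adjusted p under 0.01 there were 37 (14 and 23), with adjustment over the listed genes alone 4825 (1844 and 2981), with DESeq2 4299 (1517 and 2782), and with limma-voom 48.6% of calls were higher. Leaving out 1 library gave 0 to 3295 genes (0 to 958 higher, 0 to 2337 lower; 29.1% to 47.8% higher where any passed). Without control replicate 1 there were 3295 and without control replicate 3 there were 203 (97 and 106). Without an inoculated replicate edgeR gave 0, with smallest adjusted p of 0.135, 0.145 and 0.105. The cause was not tested, and leaving out a control also left 5 libraries. The fits without an inoculated replicate also held more genes after the filter, 5529, 5526 and 5531 against 4836 in the main fit. With all libraries, the looser filter alone lowered the calls to 676. Without control replicate 1, however, 5342 genes were fitted and the calls increased. Of 129 named genes, all chosen past the threshold, 129 lost their call without any 1 inoculated replicate, 95 without control replicate 3, 4 without control replicate 1 or 2, 40 with no filter, 20 with RLE, 17 with limma-voom and none with DESeq2.

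Whether the replicate numbers pair the samples could not be decided, because deviations from a mean of 3 libraries depend on each other. Deviations of same-numbered libraries correlated at 0.0468, 0.0584 and 0.0149 across genes, and those of other pairs at -0.0617 to 0.0229. Inoculated replicates 1 and 2 correlated best with the control of the same number, and inoculated replicate 3 with control replicate 1 (0.0169). With the replicate number as a block there were 413 genes (127 higher, 286 lower), of which 389 were shared; 58 named genes lost their call.

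Of the gene lists, 4 passed Fisher's exact test, 4 camera with a preset correlation, 0 with an estimated correlation and 28 fry. The lists that passed camera held LEA proteins and dehydrins in place of histones and the cell cycle. Fry does not compare a list with other genes. Since all members were listed for differing, its passes are largely set by the selection. With the replicate block, 7 passed camera with a preset correlation, of which none passed with an estimated correlation (smallest adjusted p = 0.788). Camera with 1 library left out passed 4 to 6. Direction tests with 1 library left out or another scaling say nothing about stability, because no listed gene changed sign without any 1 library and the list holds only changes of at least 1 on the log2 scale. Among genes with an absolute log2 fold change of at least 2, ribosomal proteins (12 higher and 12 lower; adjusted p = 0.0674) and photosynthesis (0.640) no longer passed and LEA proteins did (0.00658), as they did with 1 gene per identical description (0.0314). The pseudocount alternatives did not apply to counts.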

Other observations

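None of the lists in this paragraph passed Fisher's exact test over the 42 lists, though several had larger shares of lower genes than the listed genes as a whole. Of 52 listed calcium signalling genes 9 fell and 1 rose; LOC108986605, for a calcium-pumping ATPase of the endoplasmic reticulum, had a log2 fold change of -2.88 ± 0.38 (edgeR adjusted p = 0.0152), although under RLE, TMM and upper quartile scaling 13, 6 and 8 genes of this list passed as higher and 1, 5 and 4 as lower. Among 32 genes for sugar transport and invertases 10 fell and 2 rose, and LOC109005858 (sugar transport protein 13-like) had a log2 fold change of -4.16 ± 0.68. Of 27 nitrogen remobilisation genes 23 were lower (adjusted p = 0.131), with LOC108983585, for glutamate dehydrogenase 1, at -3.13 ± 0.50. Of 9 aquaporin genes 8 were lower and 2 fell, among them LOC108984596 (NIP6-1) at -5.45 ± 0.59. Of 27 heat shock genes 17 were lower and 10 higher, or 37.0% higher against 33.9% of other listed genes. In edgeR 10 heat shock genes fell and 1 rose, the latter being LOC109006783. It encodes a heat shock cognate protein of 70 kDa and reached 61602 ± 4297 normalized counts. Under RLE scaling 10 genes of this list passed as higher and 2 as lower. In 20 genes for glutathione S-transferases 18 were lower (adjusted p = 0.106), and in 17 for UDP-glycosyltransferases 16 were lower (adjusted p = 0.0821).

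The lists of this paragraph did not pass either. Of 14 class III peroxidase genes 4 rose and 1 fell; LOC109009576 (peroxidase 16-like) rose by 4.04 ± 0.65 on the log2 scale (edgeR adjusted p = 0.0233). In terpenoid synthesis 3 of 14 rose and 1 fell, with LOC109013467, for squalene monooxygenase, an enzyme of sterol and triterpene synthesis, up by 3.43 ± 0.49 (adjusted p = 0.0180). Of 48 cytochrome P450 genes 7 rose and 7 fell (14 and 4 under RLE, 5 and 15 with listed-count scaling). Of 24 genes for cutin, suberin and wax 3 rose and 2 fell, with LOC108999773 (3-ketoacyl-CoA synthase 2-like), at 2 counts in the controls together, 67.6-fold higher with a 95% counting interval of 18.3 to 565. In wall loosening and primary wall genes, LOC108981704, for a probable polygalacturonase without a match in the Walnut 2.0 table, rose by 3.35 ± 0.46, and LOC109009267 (expansin-A15) had a log2 fold change of -3.50 ± 0.48, with 5 genes up and 10 down of 46. Of 27 NAC factor genes 21 were lower, 4 fell and 2 rose; LOC109004745 (NAC21/22) had a log2 fold change of -6.43 ± 0.61 (adjusted p = 0.00842) and LOC109011338 (NAC53-like) rose by 2.10 ± 0.34. Of 17 genes of autophagy and senescence 15 were lower, 7 fell and 2 rose. LOC109018977, for a protein linked to senescence and dehydration, rose to 10464 ± 2342 from 1263 ± 658 normalized counts, while LOC108990877 (metacaspase-1-like) had a log2 fold change of -2.58 ± 0.51. Adjusted over the list alone, 37 of 38 fitted P450 genes passed and all fitted members of the other lists of this and the preceding paragraph. Without control replicate 3, 3 or fewer genes passed in each of these lists, and under RLE scaling the calls turned to the higher side for wall genes (17 and 5), NAC factors (5 and 2), autophagy and senescence (2 and 1) and nitrogen remobilisation (4 and 2). Without control replicate 1 they turned to the lower side for P450 genes (9 and 30), for peroxidases (4 and 6) and for cutin, suberin and wax (4 and 11), and with listed-count scaling for terpenoid synthesis (2 and 4) and for cutin, suberin and wax (2 and 9). Falls without control replicate 1 also went to 22 for calcium signalling, 21 for nitrogen remobilisation, 16 each for sugar transport and wall genes, 15 each for NAC factors and heat shock genes, 11 each for UDP-glycosyltransferases and autophagy and senescence, 9 for glutathione S-transferases and 5 for aquaporins.

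The most abundant listed transcript in inoculated replicates 2 and 3, chosen after its values were seen, was an unannotated model of 909 bases on scaffold NW_017389788.1 (114940 to 115848). It had 139160, 164313 and 240017 normalized counts in the inoculated libraries and 160, 371 and 840 in control replicates 1 to 3, and made up 3.19%, 3.62% and 4.44% of the listed counts after inoculation. In inoculated replicate 1 another listed gene made up slightly more, 3.21%. The source of the 909-base model was not tested, and reads of the fungus that align to walnut scaffolds are not excluded. Entries without a RefSeq identifier were higher in 48.4% of 312 cases, against 33.1% of the other listed genes (Fisher's exact test, two-sided, p = 6.94e-08).

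The tests below were chosen after the results were seen, apart from those of transcript length and of shared scaffolds. Splits of the 6 libraries into 3 and 3 say little here, because the genes had been listed for differing under the real grouping. That grouping gave 1637 genes past the threshold and the highest of the other 9 splits gave 0, and with 10 splits the share as high as the real one (1) cannot be under 0.05. The groups separated without overlap in 98.1% of higher and 78.0% of lower genes, against 10% by chance, though the genes were listed for differing.

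At 0 in all 3 inoculated libraries and in control replicate 1, but above 5 normalized counts in control replicates 2 and 3, were 133 genes, against 23 with the same pattern for control replicate 2 and 0 for control replicate 3. Lower depth of control replicate 1 would leave 0.00354 zeros by chance at the lower level of the other controls. Whether control replicate 1 was an inoculated branch stays open: it lay at a median of -1.67 (log2) from the inoculated mean over the higher genes and 1.72 over the lower ones, against -1.82 and -1.82 and against 2.32 and 2.84 for control replicates 2 and 3, but all these genes were listed with it counted as a control. A candidate explanation is that the sampled branches came from trees that differ in gene copies. At matched control levels 36% of 86 such genes lacked a match in the Walnut 2.0 gene table, against 16.6% of 1948 other lower genes (Fisher's exact test, two-sided, p = 2.75e-05). Matches rest on gene names and identifiers alone, so these shares do not show that the genes are missing from that assembly. Of the 133 genes 20 shared a scaffold with another one, against a median of 21 in 10000 random draws. Blocks of neighbouring genes were thus neither shown nor excluded, and which tree each branch came from is not in the labels.

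Loss of a match to the later gene table went with near absence in either group, but not with that alone. Among higher genes past the threshold 19.5% of 558 had no match, against 13.5% of 985 others (Fisher's exact test, two-sided, p = 0.00217). Among genes with a mean of at least 100 normalized counts in 1 group, 9 of 18 with at most 3 counts in the controls had no match, 27 of 124 with at most 3 counts after inoculation had none, and 340 of 3663 others had none (Fisher's exact test, two-sided, p = 1.25e-05 and 3.74e-05 against the others). Among the 133 genes, descriptions of transport proteins made up 7.52%, against 6.21% of other lower genes (Fisher's exact test, two-sided, p = 0.470).

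The rise of cytosolic ribosomal protein genes was weighed against 2 technical explanations. Short transcripts favoured in the inoculated libraries are argued against, since between 534 and 1100 bases 89.2% of 74 ribosomal protein genes were higher, compared with 35.9% of 1385 other listed genes (Fisher's exact test, two-sided, p = 2.00e-20). A shift in scaling stays open: with listed-count scaling, which moved log2 fold changes by a median of -0.55, 23 of these genes still passed as higher and 6 as lower, but the list's median of 1.41 is larger than that shift. Lack of a match in the later gene table was no more frequent among these genes than among other higher genes. The shares were 16.7% of 78 higher members and 18.2% (Fisher's exact test, two-sided, p = 0.881). Higher genes past the threshold themselves lacked a match more often than others did, at 19.5% against 13.5%. The comparison with other higher genes therefore cannot decide whether differing gene copies play a part. A difference between the branches other than the inoculation may still account for the rise, as may a response to the pathogen or reads of the fungus aligned to walnut genes, which could not be tested here; control replicates 1 to 3 varied 2.14 times as much as the inoculated ones in their coefficient of variation, and which tree each branch came from is not in the labels.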
